A study of Homo sapiens with 8 samples.

How the data were processed

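The values came from the scanner output of 8 single-colour Agilent arrays, extracted with Agilent Feature Extraction 10.7.3.1. The unit used was intensity, the background-corrected processed signal as deposited per the file headers, and the well-above-background flags of the same output were used as deposited, per the file headers, to filter dim probes. The deposited value table holds the same intensity (largest relative difference 0). Median processed signal per array was 106, 81.4, 131 and 139 in wild-type cells at 0, 12, 24 and 48 h and 123, 144, 187 and 138 in null cells. The wild-type 24 h array had a spike-in detection limit outside the range its software accepts, and no array had saturated spots.

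The arrays held 58717 non-control spots of 42405 probes. Spots of the same probe were averaged on the log2 scale, without those the software called outliers. Each array was then shifted so that its 75th percentile lay at 0. Gene symbols came from matching the probes' RefSeq accessions to a reference list of 59792 symbols (assembly GRCh38.p14, used for names alone), which named 26364 probes and left 16041 without a symbol. The probe with the highest mean signal stood for each of 19796 genes. A gene was tested if that probe was well above background on at least 2 of 8 arrays, which left 17450 genes and removed 2346. For changes at a single time a signal not well above background was raised to the floor of its array, so folds from dim baselines are lower limits. Fits and list medians used the signals as measured.

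Fits used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. With 1 array per genotype and time, the 3 treated times of a genotype stood in for replicates against its untreated array, with the spread pooled over both genotypes (4 residual degrees of freedom). The interaction term was the wild-type minus the null response, and the genotype difference took time as a term and paired the genotypes at 4 times (3 residual degrees of freedom). Changes over time thus count as spread, the p-values measure the spread between these arrays and not between repeated cultures, and the number of arrays limits the precision. A 2-fold threshold was applied to changes at each time. Each genotype had 1 untreated array, without vehicle or time-matched untreated controls, and all arrays came from 1 slide and 1 scan on which the genotypes occupied separate rows. Slide row and genotype therefore cannot be told apart.

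Before the data were examined, 16 lists with 253 genes, the tests, the main alternatives and a rule for naming genes were fixed. Of the list genes 250 were on the arrays and 242 were tested. UBE2C, NFKB2 and HIST2H2AA3 were not matched, and SPATA18, CCL20, IL1A, IFI44L, CEACAM5, LGR5, COL1A2 and COL3A1 were too dim. A list's median change was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and the percentile is a description of these arrays. The rule names the 10 genes higher and 10 lower by the smallest difference of responses over the 3 treated times. It names 6 and 6 genes per genotype by the smallest change over the 3 times, and 6 and 6 by the smallest genotype difference over the 4 times, all of these well above background on the arrays compared. It adds 5 genes per genotype from dim baselines, 3 and 3 per genotype by the 48 h minus the 12 h change, and list members as examples. Genes without an approved name of their own were passed over, and not every gene the rule selects is given.

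Alternatives were quantile normalization, median scaling, normexp background correction (offset 50) with quantile normalization, no filter on dim probes, probes well above background on all 8 arrays, the mean of a gene's probes, the deposited value table, limma with trend and robust settings, time as a term, leaving out each treated time, and thresholds of 1.5-fold and 4-fold. The normexp correction used median spot signals, since mean spot signals are not in the files. Leaving out the wild-type 24 h array, the genes bright on the untreated wild-type array alone, or the genes near clustered bright spots was chosen after the data were seen. A clustered bright spot is at least 4-fold brighter than on the other 7 arrays with at least 3 others within 8 grid steps, and a gene is near one if its spot lies within 3 steps, which held for 2272 tested genes (13.0%). Tests on simulated arrays with 200 changed genes, at a noise SD of 0.303, recovered 1.5, 46.3 and 95.5% of changes of 1, 2 and 4 in the wild-type response, with 9 false calls, and 3, 47.8 and 95.5% in the null response, with 8. For the genotype difference they recovered 16.4, 88.1 and 100%, with 7 false calls, and for the interaction 0, 4.5 and 80.3%, with 1. The noise came from the genotype fit, which takes time as a term. The response and interaction fits count changes over time as spread, so their real recovery is likely lower. Other tools were version 1.17.8 of data.table, jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9.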

Results

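HCT116 is an established human colorectal carcinoma cell line, and its transcripts were compared here in cells with wild-type p53 and in cells labelled p53-/-, called null cells from here on. Cultures of each genotype were exposed for 2 h to 2 µg/mL doxorubicin, an anthracycline that traps topoisomerase II on DNA and breaks it, and were harvested 12, 24 and 48 h later. Untreated cells of each genotype stood for 0 h, so that 8 single-colour Agilent arrays covered 8 groups with 1 array in each. The series title names the question as which genes p53 regulates in this line. The 75th percentile of the signal ran from 781 on the wild-type 12 h array to 1966 on the null 24 h array. In wild-type cells 66.9, 62.7, 71.8 and 73.1% of probes were well above background at 0, 12, 24 and 48 h, against 78.4, 78.2, 79.4 and 79.0% in null cells, and no spot was saturated. All differences are on the log2 scale, where 1 is 2-fold, and changes at a single time compare 1 array with 1 array and have no replicate check.

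Doxorubicin was followed in wild-type cells by higher levels of most of the fixed p53 target genes at every time. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was higher by 2.22, 3.65 and 4.32 at 12, 24 and 48 h. BTG2, an antiproliferative gene, was higher by 3.87, 3.69 and 3.99. BBC3, which encodes the pro-apoptotic BH3-only protein PUMA, was higher by 2.66, 2.78 and 3.02. TP53I3, a quinone oxidoreductase gene, was higher by 3.49, 6.15 and 6.61. SESN1, a stress-response sestrin, was higher by 2.90, 3.66 and 3.32. At 48 h genes of cell division and DNA replication were lower, with CENPA, the centromeric histone H3 variant, at -3.66, CDC20, an activator of the anaphase-promoting complex, at -3.20, and MCM2, a subunit of the replicative helicase, at -2.74.

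Of the 16 p53 targets in cell cycle control and feedback, 11, 14 and 14 were at least 2-fold higher at 12, 24 and 48 h in wild-type cells and 0 were lower at each time. The list's median change was 1.86, 2.01 and 2.56, at percentile 100 of the random matched lists at each time. Examples beside CDKN1A and BTG2 were TP53INP1, a stress-induced partner of p53 (3.75, 3.72 and 5.22), GADD45A, a DNA damage-inducible growth arrest gene (2.16, 1.95 and 2.80), and PHLDA3, a repressor of AKT (1.83, 2.61 and 2.70). MDM2, the ubiquitin ligase that degrades p53, was 0.65, 1.98 and 2.28 higher, with its spot near clustered bright spots on the 12 h wild-type array. Among 16 apoptosis targets 9, 12 and 14 were at least 2-fold higher, with medians of 1.39, 1.68 and 1.85 (percentile 100 at each time). TNFRSF10B, the death receptor DR5, was 1.93, 1.70 and 1.80 higher, and BAX, a pore-forming member of the BCL2 family, 0.28, 1.05 and 1.38. Of 15 measured targets in repair and metabolism 8, 13 and 13 were at least 2-fold higher, and the medians were 1.08, 1.89 and 2.57 (percentiles 99.99, 100 and 100). These included FDXR, a mitochondrial ferredoxin reductase gene (1.54, 1.85 and 2.53), XPC, a DNA damage sensor in nucleotide excision repair (0.34, 1.88 and 2.37), and RRM2B, a ribonucleotide reductase subunit (1.08, 2.10 and 2.62).

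The cell division and replication lists were mainly lower at 48 h in wild-type cells. Of 25 measured G2/M and mitosis genes 9 and 11 were at least 2-fold lower at 12 and 24 h and 24 at 48 h, and the median change was -0.72, -0.90 and -3.02 (percentile 0 each time). The member outside this count was PTTG1, or securin, at 0.78, 0.18 and 0.17. Of 26 G1/S and replication genes 1, 1 and 22 were at least 2-fold lower. That list's median was 0.16 and 0.00 at 12 and 24 h, with a sign that depended on the scaling, and -2.21 at 48 h (percentile 0). PCNA, the DNA polymerase clamp, was 0.87 to 1.21 higher at the 3 times. All 12 recombination repair genes were at least 2-fold lower at 48 h and 0 at 12 or 24 h, with medians of -0.23, -0.29 and -2.40 (percentiles 22.9, 20.3 and 0). BLM, a RecQ helicase, differed from untreated by -0.90, -0.15 and -3.01, and CHEK1, a checkpoint kinase, by -0.22, -0.54 and -2.62. Spots of 6 G2/M, 7 G1/S and 3 recombination repair genes lay near clustered bright spots on some array.

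**Figure D1:**
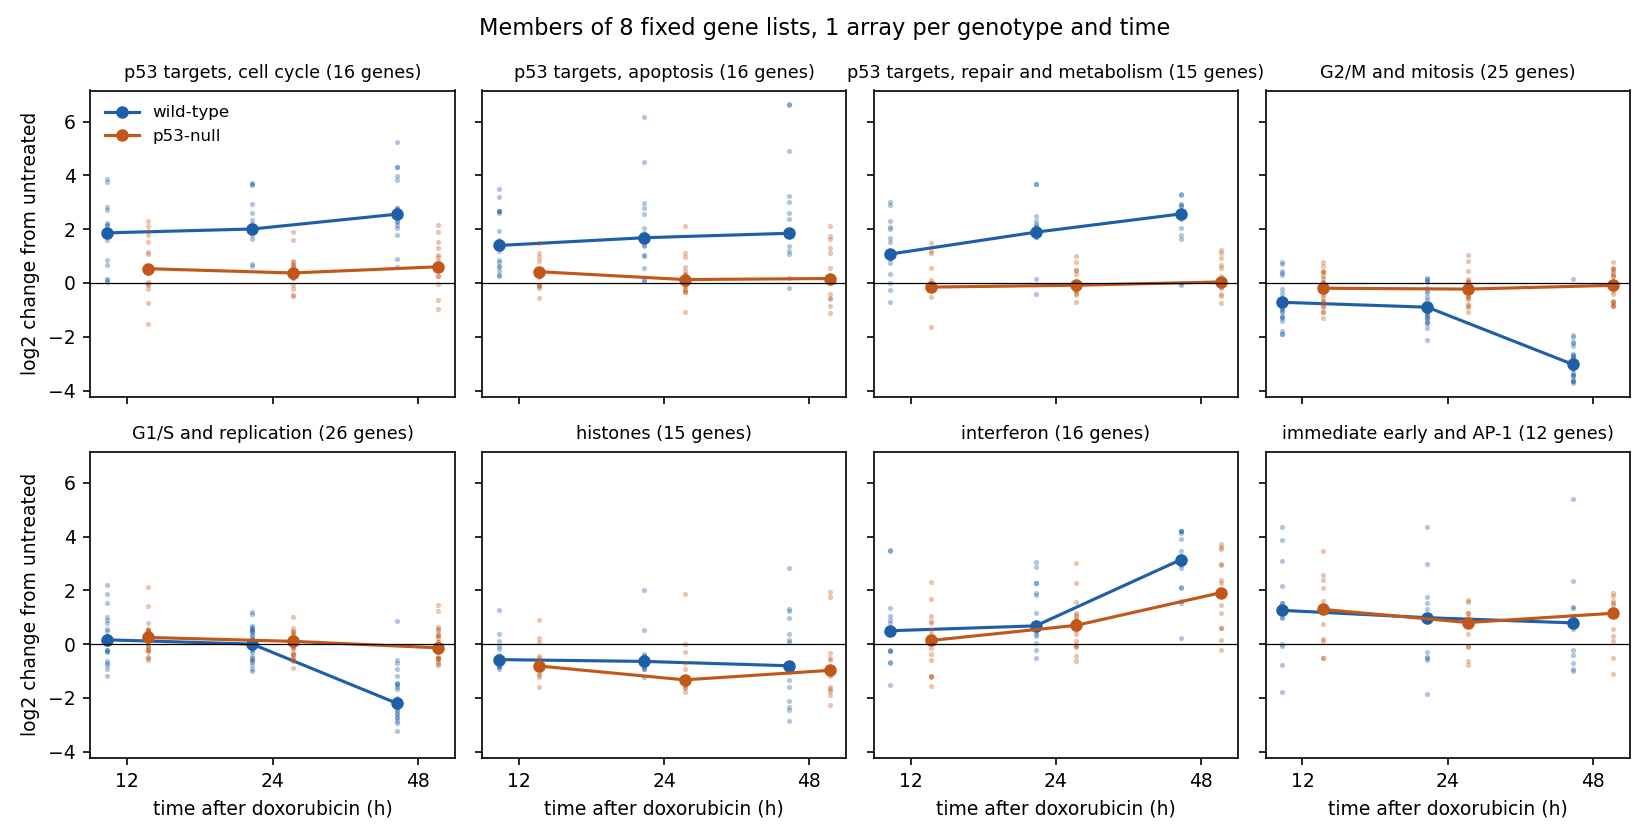
Log2 change from untreated (y axis) of each measured member of 8 fixed gene lists at 12, 24 and 48 h after doxorubicin (x axis), small points per gene and joined large points for the list's median, in wild-type and null cells. At 48 h the G2/M median lay at -3.02 in wild-type and at -0.09 in null cells, and the interferon medians at 3.14 and 1.92.

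Across all 17450 genes tested, 2003 were at least 2-fold higher and 1789 lower at 12 h in wild-type cells, 2324 and 1602 at 24 h, and 3282 and 2050 at 48 h. At all 3 times 751 genes were at least 2-fold higher and 427 lower, 1178 in all. Simulated unchanged genes sharing an untreated array gave a median of 151 and at most 178. The simulated spread came from the treated arrays alone, so it does not cover an error particular to the untreated array. The simulated genes were also counted without the background rule, so the counts are not alike. By the naming rule the sustained increases included EGR2, a zinc finger transcription factor (4.35, 4.35 and 5.39), and CBS, cystathionine beta-synthase (3.99, 6.88 and 8.67). Others were TENT5C, a poly(A) polymerase (4.74, 3.93 and 3.96), GRIN2C, an NMDA receptor subunit (at least 3.91 at each time), and MYBPHL, a myosin-binding protein H homolog (3.89, 5.94 and 4.52). Their limma adjusted p-values ran from 0.0719 for TENT5C to 0.228 for CBS, each gene being higher at 3 of 3 times. Of the 6 decreases, ENOX1, an ecto-NOX oxidoreductase gene, differed from untreated by -3.48, -2.96 and -2.87. The other 5, with SORBS2, FAM86C2P, PLA2G4F and EGFEM1P among them, were at least 4-fold brighter on the untreated wild-type array than on every other array, and 4 of the 5, all but SORBS2, had spots near clustered bright spots there. From baselines not well above background, EDN2, endothelin 2, reached at least 24.1-, 97.0- and 168-fold at 12, 24 and 48 h. SCN3B, a sodium channel subunit gene, reached at least 23.9-, 72.5- and 140-fold, and CHGA, chromogranin A, at least 21.9-, 29.2- and 55.9-fold. SORCS2, a sortilin-family receptor gene, reached at least 41.7-, 639- and 720-fold, with its spot near clustered bright spots on the untreated and 12 h arrays. CFTR, a chloride channel gene, reached at least 27.7-, 52.4- and 85.1-fold, near such spots at 12 and 24 h. The widest gains from 12 to 48 h were those of CCL26, a chemokine (-0.25, 4.62 and 6.63), and LGALS9C, a galectin gene with close paralogs (0.62, 4.10 and 6.81). H19, an imprinted noncoding RNA whose spot lies near clustered bright spots at 48 h, was next to them (1.65, 5.47 and 7.83). HEY1, a Notch-responsive repressor gene, went the other way (4.21, 2.15 and -0.66).

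**Figure D2:**
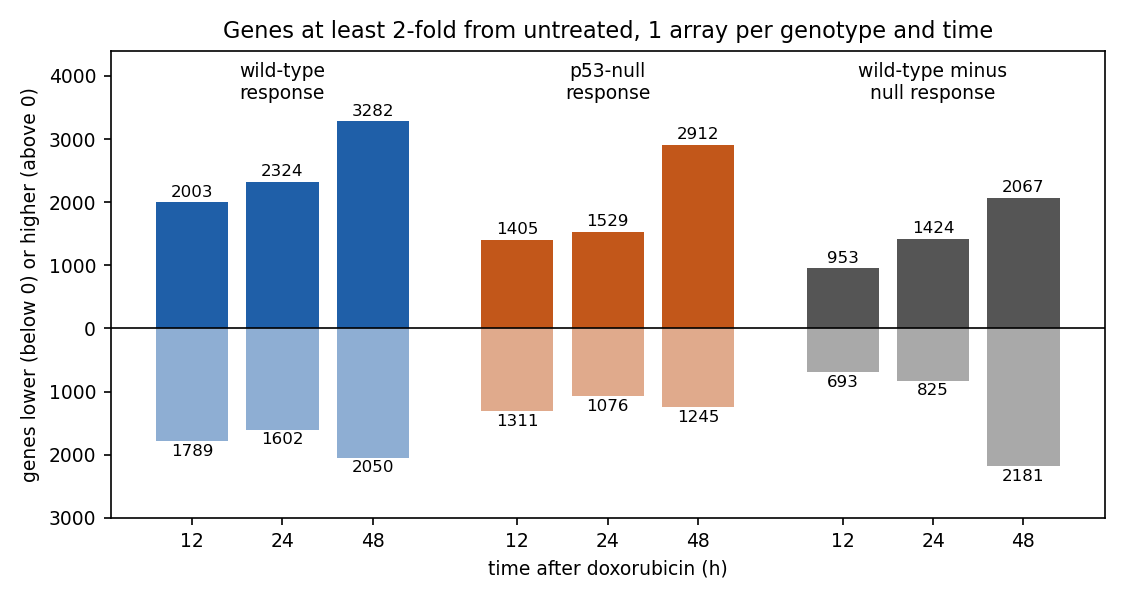
Number of genes at least 2-fold higher (bars above 0) or lower (paler bars below 0) at 12, 24 and 48 h after doxorubicin (x axis), in wild-type cells, in null cells and for the wild-type minus null response. Counts rise to 3282 higher and 2050 lower in wild-type cells at 48 h, against 2912 and 1245 in null cells, with 1 array per genotype and time.

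Taking the 3 treated times as the spread, limma called 18 of 17450 genes in wild-type cells, 9 higher and 9 lower, with a Benjamini-Hochberg adjusted p of at least 0.0254. BTG2 rose by 3.85 (SE 0.44, higher at 3 of 3 times, limma adjusted p = 0.0499) and PGF, placental growth factor, by 3.86 (SE 0.37, 3 of 3, adjusted p = 0.0419). In the same limma fit ADAMTS4, an aggrecanase gene, and CHGA rose as well (3 of 3, adjusted p = 0.0457 for each), with untreated signals not well above background, so the size of their rise is not given. CDIP1, LINC00324, RTL5, FST and ZNF699, named after their values were seen except for FST, were the other 5 that rose, FST and ZNF699 with spots near clustered bright spots and LINC00324, FST and ZNF699 with dim baselines as well. The 9 lower genes were each at least 4-fold brighter on the untreated wild-type array than on every other array, 8 of them near clustered bright spots there. Leaving out genes near such spots does not change the values of the other higher genes, but adjusted p-values depend on all genes tested. Adjusted over the list alone, 11 of 16 cell cycle targets, 8 of 16 apoptosis targets and 7 of 15 repair and metabolism targets rose in wild-type cells, against 1, 0 and 0 over all genes. For CDKN1A the mean change was 3.40 (SE 0.74, 3 of 3 times, adjusted p = 0.00521 over its list and 0.212 over all genes), and for BBC3 2.82 (SE 0.51, 3 of 3, adjusted p = 0.00680 and 0.141). The count of 18 ended at 0 without the 24 h arrays, without the 48 h arrays, or without the genes near clustered bright spots, and at 1 without the wild-type 24 h array alone. Without the 24 h arrays the list counts were 10, 0 and 3, and without the 12 h arrays 14, 12 and 13.

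In null cells 12 of 16 interferon genes were at least 2-fold higher at 48 h and 10 of 15 histone genes lower at 24 h. CDKN1A was higher by 2.11, 1.90 and 2.15 in null cells, TP53INP1 by 2.32, 1.59 and 1.52, and CCNG2, an atypical cyclin, by 1.91, 0.81 and 1.29. BBC3 differed from untreated by -0.58, -0.35 and 0.56, and SESN1 by 1.21, 0.47 and -0.50. The medians of the cell cycle targets were 0.53, 0.37 and 0.60 (percentiles 99.9, 99.7 and 99.5), with 7, 2 and 5 of 16 at least 2-fold higher and 1 lower at 12 h. The apoptosis targets had medians of 0.42, 0.13 and 0.17 (percentiles 99.7, 92.3 and 63.7; 2, 2 and 5 higher). Those of the repair and metabolism targets were -0.15, -0.08 and 0.04, the last 2 with a sign that depended on the scaling (percentiles 23.9, 49.5 and 49.2; 3, 0 and 2 higher). The G2/M median was -0.20, -0.23 and -0.09, of which the 24 h value turned to 0.00 with normexp background correction, and 3, 1 and 0 of 25 members were at least 2-fold lower. G1/S and replication genes had medians of 0.25, 0.10 and -0.14 in null cells. Those of the recombination repair genes were -0.23, 0.23 and 0.11, the last turning to -0.04 under median scaling, and 0 members of either list were lower by 2-fold at any time.

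Genes past 2-fold in null cells numbered 1405 higher and 1311 lower at 12 h, 1529 and 1076 at 24 h, and 2912 and 1245 at 48 h. At all 3 times 463 were higher and 235 lower, 698 in all, against at most 178 in the same simulation. That simulation has the limits given above and does not cover an error of the untreated null array. CXCR4, a chemokine receptor gene, was higher by 3.25, 2.86 and 3.68 in null and by 3.71, 3.31 and 2.75 in wild-type cells. CCN2, connective tissue growth factor, was higher by 2.46, 2.71 and 2.85 in null and by 2.28, 3.02 and 2.94 in wild-type cells. TEX14, a germ-cell bridge protein gene (3.22, 2.84 and 2.96), and NEFH, the neurofilament heavy chain (4.02, 3.56 and 2.64), were higher in null cells as well. PDE6G, a phosphodiesterase subunit gene near clustered bright spots on the wild-type 12 h array, was higher by 3.74, 4.56 and 4.98. Among the decreases SLC19A1, the reduced folate carrier, differed from untreated by -2.66, -3.43 and -2.75, and H1-4, a linker histone gene, by -2.59, -2.41 and -2.52. The probe assigned to RNA18SN5, an 18S ribosomal RNA gene, differed from untreated by -3.57, -3.65 and -3.33 in null and by -2.34, -2.65 and -3.14 in wild-type cells. Differences in priming or purification between the RNA samples were not tested. PLA2G2F, a phospholipase gene, TMEM119 and TNFRSF9 were at least 4-fold brighter on the untreated null array than on every other array, and the last 2 lay near clustered bright spots there. From dim baselines C9orf152 reached at least 62.2-, 13.4- and 15.1-fold, ADAMTS4 at least 9.51-fold at each time, and EGR3, an early growth response factor, at least 11.4-, 9.63- and 11.4-fold. BFSP2, a lens filament gene from a dim baseline (at least 1.09, 3.84 and 8.11), and KRT9, a keratin gene (0.16, 4.03 and 5.57), had among the widest gains from 12 to 48 h, and RSRP1 (3.30, 0.99 and -0.06) among the widest losses. Limma called 0 of 17450 genes in null cells. An unadjusted p under 0.05 went to 928 genes (5.32%), the smallest adjusted p was 0.117, and every alternative fit also called 0. Adjusted over the list alone, 0 of the p53 targets passed in null cells.

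The responses of both genotypes went together across genes. Pearson's r between the wild-type and null changes, across 17450 genes that are not independent replicates, was 0.645, 0.564 and 0.589 at 12, 24 and 48 h, with Spearman's rho of 0.618, 0.578 and 0.543. At 48 h 1744 genes were at least 2-fold higher in both genotypes where independent lists of these sizes would share 548, 474 were lower in both (146 if independent), and 88 went opposite ways.

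The part of the response that differed between genotypes had its widest list medians in the p53 targets at 12 and 24 h and in the G2/M genes at 48 h. BTG2 was higher in the wild-type response than in the null response by 2.35, 3.03 and 3.01, BBC3 by 3.24, 3.13 and 2.46. MDM2 differed by 2.19, 2.43 and 2.30, and SESN1 by 1.70, 3.19 and 3.82. At 12 and 24 h the MDM2 difference exceeded its rise in wild-type cells, so part of it was a fall in null cells. The MDM2 spot lay near clustered bright spots on the wild-type 12 h array. CDKN1A differed by 0.11, 1.75 and 2.18. The medians of the difference were 1.16, 1.81 and 2.09 for the cell cycle targets, 0.99, 1.49 and 1.73 for the apoptosis targets and 1.09, 2.04 and 2.15 for the repair and metabolism targets, all at percentile 100. For the G2/M genes they were -0.52, -0.69 and -2.90, and at 48 h -2.04 for the G1/S and -2.37 for the recombination repair genes, all at percentile 0. At 48 h 24 of 25 G2/M genes, 24 of 26 G1/S genes and 12 of 12 recombination repair genes were at least 2-fold lower in the wild-type response than in the null response.

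**Figure D3:**
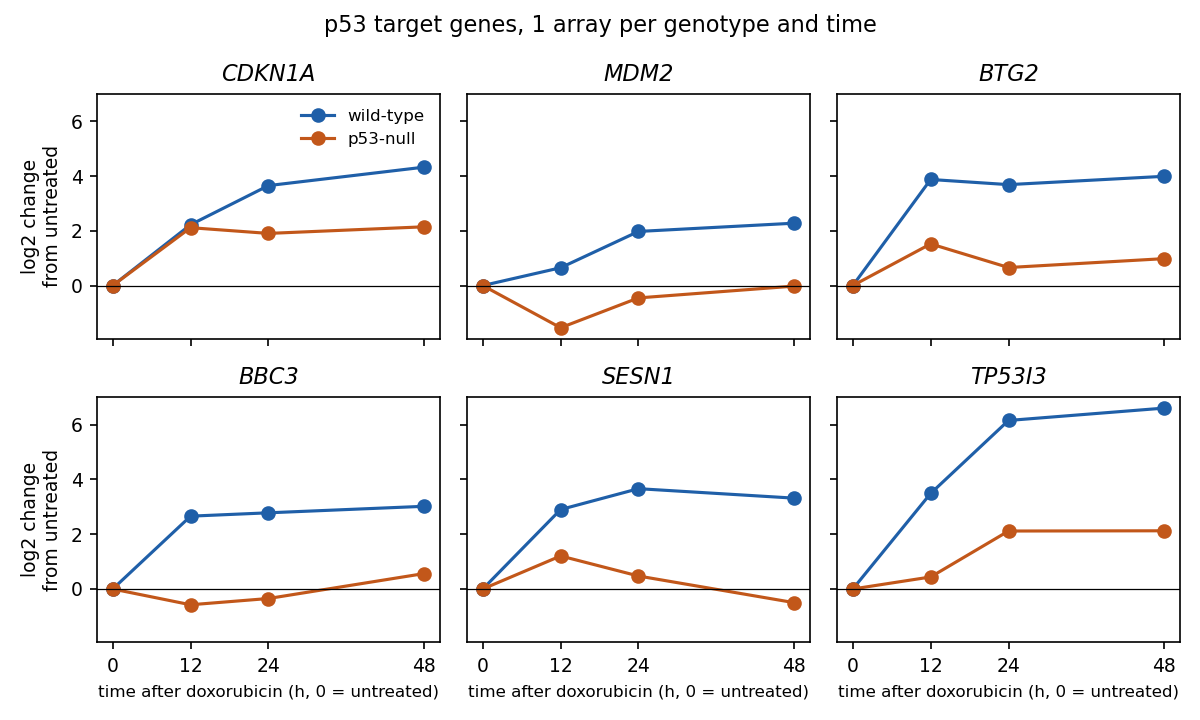
Log2 change from untreated (y axis) against hours after doxorubicin (x axis) for 6 p53 target genes in wild-type and null cells, 1 array per point and untreated cells set to 0. CDKN1A is higher in both genotypes, by 4.32 and 2.15 at 48 h, while BBC3 and SESN1 differ at 48 h by 2.46 and 3.82.

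The 10 genes with the largest sustained excess in the wild-type response, well above background on all arrays, included AKR1B10, MYBPHL, GRIN2C, TP53I3, NUPR1, AKR1B15, NTN1, PGF and LCN15. AKR1B10, an aldo-keto reductase gene, differed by 3.70, 5.07 and 4.34, and its close paralog AKR1B15 by 2.93, 4.83 and 4.31; cross-hybridisation between their probes was not tested. NUPR1, a stress-induced chromatin protein gene, differed by 3.00, 5.88 and 3.58, and LCN15, a lipocalin gene, by 2.67, 5.22 and 4.64. NTN1, or netrin 1, differed by 2.71, 4.28 and 4.45, with its spot near clustered bright spots on the wild-type 12 h array. Of the 10 genes with the largest sustained deficit, 7 had spots near clustered bright spots on the untreated wild-type array, PLA2G4F, EGFEM1P, RGS2, FAM86C2P, GGT5 and RALGPS2 among them. HOXB8, a homeobox gene, differed by -1.92, -3.39 and -2.35, and STAMBPL1, a deubiquitinase gene, by -1.90, -2.27 and -1.66, while SORBS2 was bright on the untreated wild-type array alone. The difference passed 2-fold at 12, 24 and 48 h for 953, 1424 and 2067 genes higher in the wild-type response and for 693, 825 and 2181 lower. At all 3 times it did for 304 higher and 140 lower genes, 444 in all, against a median of 467.5 and at most 517 in simulated unchanged arrays. The simulated spread was taken from these arrays and includes genotype differences that change over time. The simulated genes were also counted without the background rule. The 2 counts are therefore not alike, and the comparison does not tell whether the responses differ.

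The interaction term, fitted with limma, called 0 of 17450 genes. The smallest adjusted p was 0.144, 246 genes (1.41%) had an unadjusted p under 0.05. The median standard error of 0.74 was wider than in the other fits. On simulated data with this design it recovered 0, 4.5 and 80.3% of differences of 1, 2 and 4. The simulated noise came from the genotype fit, which takes time as a term, so recovery on the real arrays is likely lower. Adjusted over the list alone, BTG2 passed (2.80 higher in the wild-type response, SE 0.62, 3 of 3 times, limma adjusted p = 0.0438 over its list), though not over all genes, and 0 of the other p53 targets did. Unadjusted p-values under 0.05 went to 8, 5 and 5 members of the 3 p53 lists, with 15 of 16, 16 of 16 and 14 of 15 differences above 0. The BTG2 call ended under median scaling (adjusted p = 0.068) and without the 24 h or the 48 h arrays (0.275 and 0.0986), and without the wild-type 24 h array (0.0987). Time as a term gave 7, 7 and 0 members of the 3 lists, and leaving out the 12 h arrays gave 5, 5 and 7.

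Genotypes were also compared over all 4 times, untreated cells included. PXDN, a peroxidase gene of the extracellular matrix, was 6.23 higher in wild-type cells (SE 0.43, 4 of 4 times, limma adjusted p = 0.00928), and MAGEA9, a cancer-testis antigen gene, 4.65 higher (SE 0.17, 4 of 4, adjusted p = 0.00118). CASP4 and CASP5, neighbouring genes of inflammatory caspases, were 4.92 and 4.41 higher (SE 0.35 and 0.25, 4 of 4, adjusted p = 0.00928 for each). WNT16, a secreted Wnt ligand gene, was -3.58 (SE 0.26, lower at 4 of 4, adjusted p = 0.00971) and ACSL5, a long-chain acyl-CoA synthetase gene, -2.21 (SE 0.20, 4 of 4, adjusted p = 0.0151). In untreated cells PXDN already differed by 4.97, MAGEA9 by 4.75 and CASP4 by 5.84. SYK, a tyrosine kinase gene (3.24 to 4.62 over the 4 times, adjusted p = 0.00928), and ZC4H2, a zinc finger gene (-2.54, adjusted p = 0.00971), also passed at 4 of 4 times in the same limma fit but lay near clustered bright spots on 2 wild-type arrays each. The other named genes of this limma fit were PLCL2 (4.19, adjusted p = 0.0127), STXBP6 (-3.19, adjusted p = 0.0146), PKIB (-2.46, adjusted p = 0.0336) and ZNF100 (-2.24, adjusted p = 0.0267), each with 1 direction at 4 of 4 times. The MAGEA9 call held in 15 of 15 alternatives, and those of PXDN, CASP4, CASP5, STXBP6 and ZNF100 in 12 of 15. Such counts include the deposited value table, which holds equal values and could not change a call. Calls of WNT16, ACSL5 and PKIB held in 11 of 15, PLCL2 in 10 of 15, and SYK and ZC4H2 in 10 and 11 of 14.

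In the same fit, adjusted over the list alone, 12 of 16 cell cycle targets, 7 of 16 apoptosis targets and 11 of 15 repair and metabolism targets were higher in wild-type cells, against 1, 2 and 1 over all genes. The counts over the list alone were 8, 5 and 8 without the 24 h arrays and 13, 12 and 13 with the treated arrays alone. CDKN1A differed by 2.97 (SE 0.42, 4 of 4 times, limma adjusted p = 0.0427) and by 1.96 before treatment, and DDB2, a nucleotide excision repair gene, by 1.69 (SE 0.24, 4 of 4, adjusted p = 0.0431). Each of these 2 calls held in 7 of 15 alternatives. FAS, a death receptor gene near clustered bright spots, differed by 2.36 (SE 0.31, 4 of 4, adjusted p = 0.0358) and TNFRSF10C, a decoy receptor gene, was higher at 4 of 4 times but well above background on only 2 of the 4 null arrays (adjusted p = 0.00928). These 2 calls held in 7 and 10 of 14 alternatives. Before treatment the 3 p53 lists had median differences of 0.32, 0.10 and 0.28 (percentiles 99.8, 66.2 and 98.9). Of the G2/M genes 5 were lower in wild-type cells over the list alone and 0 over all genes, among them TOP2A, topoisomerase II alpha (-2.06, SE 0.40, lower at 4 of 4), and AURKA, a mitotic kinase (-1.26, SE 0.33, 4 of 4). The G2/M median difference was -0.14, -0.58, -0.77 and -3.11 at 0, 12, 24 and 48 h. At least 2-fold lower at these times were 0, 9, 10 and 24 of 25 members, so the difference was small before treatment.

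Across all genes this fit called 233, of which 163 were higher and 70 lower in wild-type cells, and 24 of the 163 and 5 of the 70 lay near clustered bright spots. At 0 h alone 540 genes were at least 2-fold higher and 482 lower in wild-type cells. The 4 wild-type arrays lay in 1 row of the slide and the 4 null arrays in the other, so slide row and genotype cannot be told apart, and every null array had more probes well above background than any wild-type array. The count was 2 without either the 12 h or the 24 h arrays, 2 without the wild-type 24 h array alone, and 105 without the 48 h arrays.

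Interferon-related genes were higher at 48 h in both genotypes. Of 16 measured members 4, 7 and 15 were at least 2-fold higher at 12, 24 and 48 h in wild-type cells and 2, 6 and 12 in null cells. At 12 h 1 member was at least 2-fold lower in wild-type and 4 in null cells, and 0 were at 24 and 48 h. The medians were 0.50, 0.68 and 3.14 (percentiles 97.9, 99.7 and 100) in wild-type and 0.14, 0.70 and 1.92 (percentiles 86.9, 99.8 and 100) in null cells. With normexp they were 0.18, 0.56 and 2.37 in wild-type and 0.09, 0.36 and 1.24 in null cells. IFIT2, which encodes an RNA-binding interferon effector, was higher by 0.79, 1.16 and 4.20 in wild-type and by 0.54, 0.91 and 3.73 in null cells, and IFIH1, the RNA sensor MDA5, by 0.91, 1.83 and 3.28 and by 0.38, 1.09 and 2.26. IRF7, a transcription factor of the interferon response, rose in each genotype in limma's test adjusted over the list alone (3.09, SE 0.46, 3 of 3 times, adjusted p = 0.00390 in wild-type and 2.52, SE 0.46, 3 of 3, adjusted p = 0.0136 in null cells). Over all genes 0 members passed. The median difference of the responses at 48 h was 0.98 (percentile 99.99), and the interaction called 0 members over the list alone. Over the 4 times 6 members were higher in wild-type cells over the list alone and 1, IFIT2, over all genes (1.32, SE 0.17, 4 of 4, adjusted p = 0.0341). The IFIT2 call held in 8 of 15 alternatives.

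NF-kB and inflammatory genes had medians of 0.97, 0.75 and 2.28 in wild-type cells (percentiles 99.9, 99.0 and 100) and 0.43, 0.43 and 0.99 in null cells (98.9, 97.4 and 99.3). With normexp background correction they were 0.28, 0.19 and 0.94 in wild-type and 0.21, 0.22 and 0.56 in null cells. The median difference of the responses at 12 h turned from 0.32 to -0.01. Of 13 members 4, 4 and 8 were at least 2-fold higher in wild-type and 4, 2 and 6 in null cells. Spots of 5 members lay near clustered bright spots, 2 of them on the untreated wild-type array. TNFAIP3, the ubiquitin-editing enzyme A20, was higher by 1.51, 1.62 and 2.84 in wild-type and by 1.70, 0.80 and 1.02 in null cells, and CXCL1, a chemokine, by 1.94, 1.28 and 2.54 and by 0.42, 0.66 and 1.66. Adjusted over the list alone, 0 members passed in either response (smallest limma adjusted p = 0.135 and 0.494, with 4 and 0 unadjusted p-values under 0.05). Over the 4 times 3 were higher in wild-type cells over the list alone and 2 over all genes. These were LIF, a cytokine of the interleukin 6 family (2.26, SE 0.25, 4 of 4, limma adjusted p = 0.0292), and BIRC3, an inhibitor of apoptosis (1.19, SE 0.19, 4 of 4, adjusted p = 0.0494). The call over all genes held in 10 of 15 alternatives for LIF and in 5 of 15 for BIRC3.

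Immediate early and AP-1 genes had medians above 0 in both genotypes from 12 h on. Medians were 1.26, 0.98 and 0.79 in wild-type cells (percentiles 100, 100 and 99.8) and 1.29, 0.80 and 1.15 in null cells (percentile 100 each), with 6, 6 and 6 and 7, 5 and 7 of 12 at least 2-fold higher. Lower by 2-fold were 1, 1 and 1 in wild-type and 0, 0 and 1 in null cells. FOSB, an AP-1 subunit, was higher by 3.11, 1.77 and 1.01 in wild-type and by 3.48, 1.58 and 1.61 in null cells. Over the list alone EGR2, ATF3, a stress-induced bZIP factor, JUNB and DUSP1, a MAP kinase phosphatase, rose in wild-type cells and MYC fell, against 0 over all genes. The mean changes were 4.70, 3.07, 1.13, 1.29 and -1.52, with limma adjusted p = 0.00418, 0.00899, 0.0427, 0.0427 and 0.0427, each at 3 of 3 times, and MYC has a spot near clustered bright spots at 48 h. In null cells 0 passed over the list alone (smallest limma adjusted p = 0.0779, 4 unadjusted p-values under 0.05), and the interaction called 0 (smallest 0.256, 1 unadjusted).

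Histone genes and genes of endoplasmic reticulum and integrated stress had medians below 0 in both genotypes. Of 15 histone genes, many of them close paralogs, 0, 1 and 7 were at least 2-fold lower in wild-type cells and 4, 10 and 7 in null cells. Those at least 2-fold higher numbered 1, 1 and 3 and 0, 1 and 2. The RNA18SN5 probe lay lower on the same arrays, and a shared source in RNA priming or purification was not tested. Their medians were -0.57, -0.64 and -0.80 (percentiles 0.19, 0.60 and 0.49) and -0.81, -1.33 and -0.97 (percentile 0 each). H2AC6 differed from untreated by -0.91, -0.66 and -1.34 in wild-type and -1.15, -1.64 and -2.26 in null cells, while H2AJ, a histone H2A variant gene, was higher by 1.28, 2.01 and 1.24 and by 0.88, 1.86 and 1.93. The stress list of 12 had medians of -0.58, -0.86 and -0.44 in wild-type cells (percentiles 0.080, 0.080 and 12.5; 3, 5 and 4 lower, 1, 0 and 2 higher) and -0.75, -1.23 and -0.59 in null cells (percentiles 0, 0 and 0.15; 3, 8 and 4 lower, 1, 0 and 0 higher). TRIB3, a pseudokinase gene under ATF4, differed from untreated by -1.20, -2.01 and -1.93 in wild-type and -1.61, -2.14 and -1.38 in null cells, and PSAT1, an enzyme of serine synthesis, by -0.70, -2.00 and -1.55 and by -0.87, -2.01 and -1.46. Limma called 0 members of either list in either response over the list alone (unadjusted p under 0.05 for 1 and 5 histone and 1 and 2 stress genes). DDIT4 and CHAC1, both stress genes, were higher in wild-type cells over the 4 times over the list alone (2.13 and 0.72, 4 of 4 times, limma adjusted p = 0.0112 and 0.0453). DDIT4 has a spot near clustered bright spots on the wild-type 24 h array.

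Ribosomal protein genes had medians of 0.34, -0.36 and -0.33 in wild-type cells (percentiles 42.7, 23.5 and 20.8), the 12 h value turning negative under quantile normalization (-0.16), and -0.08, -0.52 and -0.21 in null cells (percentiles 19.8, 8.03 and 5.32). Cholesterol synthesis genes had medians of -0.04, -0.16 and -0.53 in wild-type (percentiles 43.5, 47.4 and 6.43) and -0.09, -0.13 and -0.14 in null cells (38.6, 36.5 and 21.1). HMGCS1, an early enzyme of that pathway, was -1.56 over the 4 times (SE 0.31, lower in wild-type cells at 4 of 4, limma adjusted p = 0.0275 over the list alone). The p53 family and regulators had medians of -0.10, -0.49 and -1.27 in wild-type (percentiles 33.6, 5.18 and 0.010) and -0.62, -0.36 and -0.73 in null cells (1.57, 9.02 and 0.34). With normexp they were 0.01, -0.25 and -0.81 in wild-type and -0.17, -0.23 and -0.33 in null cells. MDM4, an inhibitory partner of p53, fell in both genotypes over the list alone (-1.81 and -1.77, SE 0.41, 3 of 3 times, limma adjusted p = 0.0222 and 0.0257). Markers of colon epithelium had medians of 0.36, 0.16 and 0.63 in wild-type (percentiles 77.1, 92.9 and 99.0) and 0.01, -0.13 and 0.68 in null cells (60.6, 54.1 and 99.3), the null 24 h value turning positive under quantile normalization (0.21). At 48 h 6 of 14 were at least 2-fold higher in each. With normexp the colon medians were 0.15, 0.18 and 0.28 in wild-type and 0.02, 0.11 and 0.37 in null cells. CDH1, E-cadherin, was higher by 0.59, 1.27 and 2.48 and by 0.47, 0.88 and 1.85. Markers of other cell types, of which 8 of 14 lay near clustered bright spots, had medians of 0.52, 0.42 and 0.39 in wild-type (percentiles 96.3, 92.5 and 77.1; 0.16, 0.22 and 0.14 with normexp) and 0.20, 0.36 and 0.89 in null cells (percentiles 93.5, 95.7 and 98.7; 0.14, 0.27 and 0.48 with normexp). At 48 h 5 of 14 were at least 2-fold higher in each, and 0 passed in the wild-type, null, interaction or genotype test of limma over the list alone (1, 3, 0 and 0 unadjusted p-values under 0.05).

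**Figure D4:**
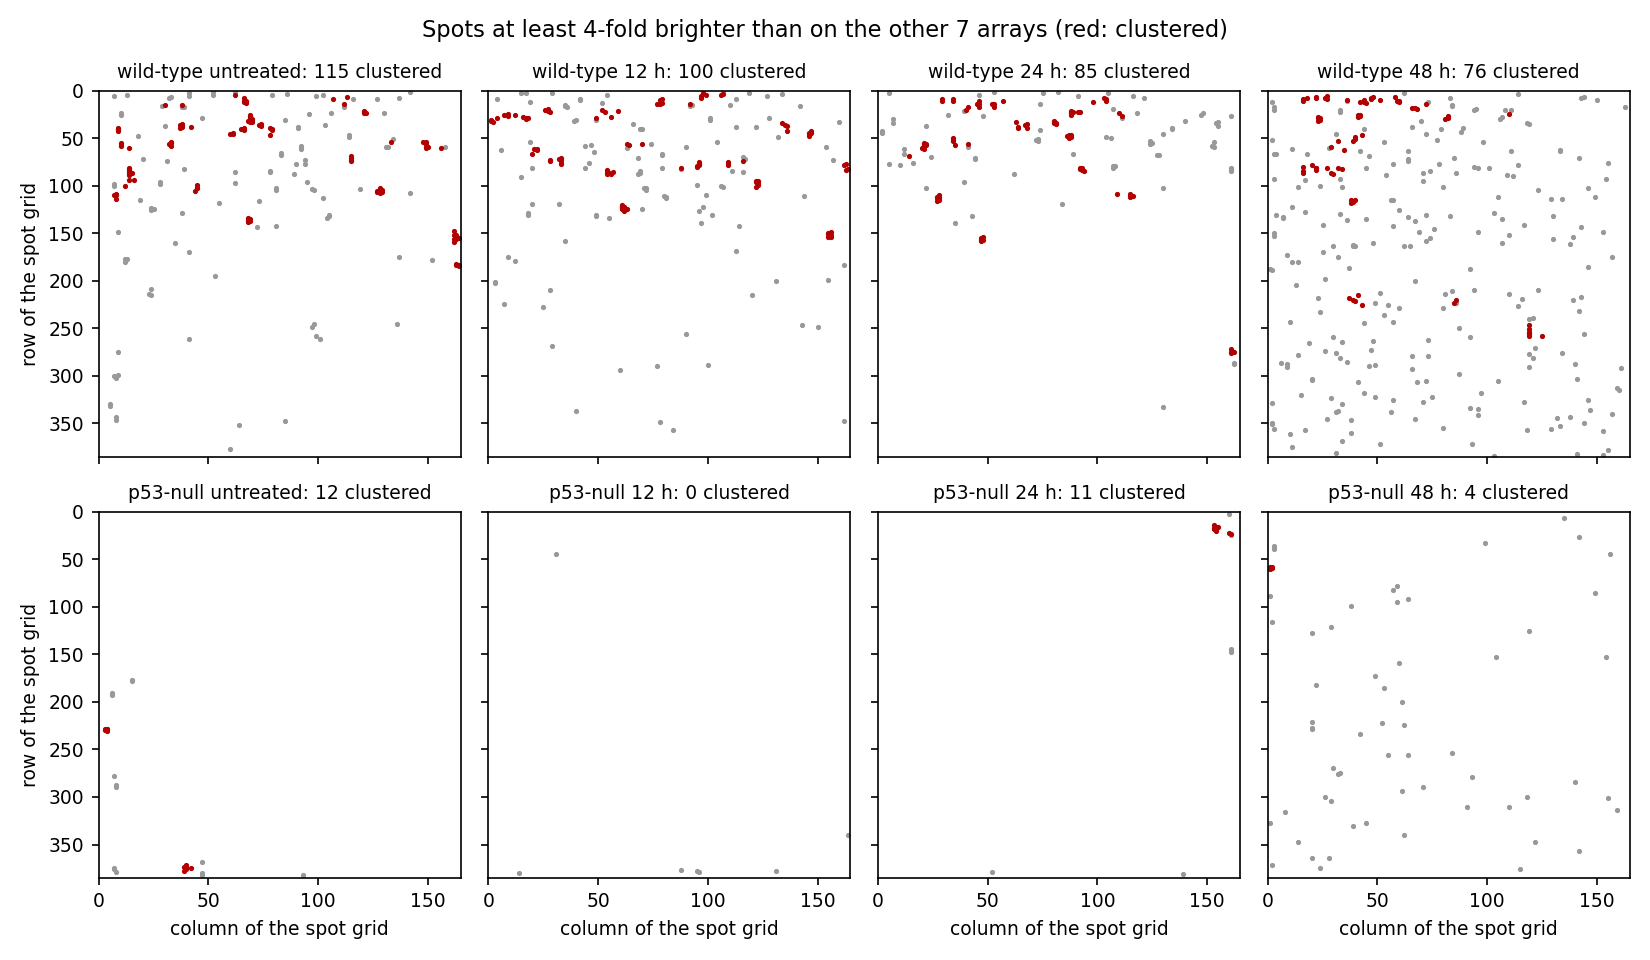
Spots at least 4-fold brighter on an array than on the other 7, drawn at their row and column of the spot grid for each of the 8 arrays, grey where scattered and red where at least 3 others lay within 8 grid steps. The 4 wild-type arrays hold 115, 100, 85 and 76 clustered spots at 0, 12, 24 and 48 h and the null arrays 12, 0, 11 and 4.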

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

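The tests for wild-type cells in the null samples, for array scaling and for splits within times were written after the results were seen, and so were the choices of the opposite genes and of the probes without a symbol named here.

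BTG2 differed between genotypes in its response to doxorubicin by 2.80, adjusted over its list alone (limma adjusted p = 0.0438). The call did not pass over all genes and ended under median scaling and without the 24 h, the 48 h or the wild-type 24 h arrays. ACKR3, an atypical chemokine receptor gene, and PTPRVP, a phosphatase pseudogene, were the 2 genes at least 2-fold higher at all 3 times in wild-type cells and lower in null cells. ACKR3 differed from untreated by 2.60, 2.53 and 2.59 against -3.06, -3.11 and -1.70, and PTPRVP by 1.47, 1.54 and 2.43 against -2.32, -1.96 and -2.07. Neither was well above background on the untreated wild-type array, so their wild-type changes are lower limits. SNX31, a sorting nexin gene, was the 1 gene going the other way (-3.16, -4.11 and -4.50 against at least 2.38, 1.44 and 2.73 from a dim null baseline), and it is among the genes bright on the untreated wild-type array alone. The difference was not tested for these 3 genes beyond the limma interaction, which called 0 of 17450 genes (246 with an unadjusted p under 0.05).

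Of 11892 probes without a gene symbol that were tested, 221 were at least 2-fold higher at all 3 times in wild-type cells and 153 in null cells, with 277 and 193 lower. Of the lower probes 50 and 4 were at least 4-fold brighter on the untreated array of their genotype than on every other array, and the 50 are among the probes taken below as a likely blemish. In wild-type cells 4.19% of these probes, the bright ones included, moved at all 3 times, against 6.75% of the named genes. In null cells 2.91% of the probes did, against 4% of the named genes. A long noncoding RNA probe, A_19_P00321585 on chromosome 4 (90602655 to 90605092, hg19), differed from untreated by 4.06, 4.52 and 5.68 in wild-type and by -0.09, -0.23 and 0.13 in null cells. It was not well above background on the untreated wild-type and null 12 h arrays, so its wild-type changes are lower limits. The interval of A_19_P00318649, 90548934 to 90641190 on the same chromosome and strand, contains that of the first probe, so these are not separate loci. A_19_P00318649 differed from untreated by 2.99, 4.27 and 4.67 in wild-type and by -0.19, -0.21 and 1.78 in null cells. It was not well above background on the null 12 h array.

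The first pattern weighed is the set of 171 probes at least 4-fold brighter on the untreated wild-type array than on every other array, the source of all 9 lower calls in wild-type cells. Transcripts present in that sample alone are argued against by 58 other probes of the same genes, whose median excess was 0.00843 (quartiles -0.418 and 0.503). Many of the 58 were not well above background on that array and several share a gene, which weakens this argument. Of the 171 bright probes 6 were printed on several spots, and 0% of these showed the excess on every spot. The median distance from a bright spot to the nearest other, 2.24 grid steps against 9.22 for random spots, lay at percentile 0 of 1000 random draws. A local blemish on the array is therefore a likely source of these signals. Clustered spots were most frequent on the 4 arrays of the wild-type row (76 to 115, against 0 to 12 on the null arrays), and 736 genes lay near them on the untreated wild-type array.

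The second pattern is the 233 genes called between genotypes. The planned count took all 32 splits of the 8 arrays into 4 and 4 that leave time free to be fitted, of which 1, the real one, gave as many calls and the highest of the others 3. Since the fit pairs the genotypes by time, only 8 of these splits keep its design, which are too few for a share under 0.05. Of the 8 splits 1, the real one, gave as many calls, and the highest other gave 0. A difference between the slide rows cannot be told apart from genotype, because every wild-type array lay in 1 row. The genotype itself, and differences between the cell lines unrelated to p53, remain open and untested.

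The third pattern is the 12 members of the p53 target lists at least 2-fold higher at 12 h in null cells, CDKN1A and TP53INP1 among them. Wild-type cells mixed into the treated null sample would need a median share of 19.5%. That predicts a median rise of 1.91 in 14 genes far higher in untreated wild-type than in untreated null cells. The measured median was -0.0940 (quartiles -0.519 and 0.277). These genes were called between genotypes over all 4 times, with the null 12 h array in the fit. Such a choice favours genes that did not rise there, so the test cannot exclude mixing. The smallest median rise of the members over 4 scalings was 1.23, which decides nothing about array scaling because the members were chosen for their rise. A shift of the whole array would raise other genes alike, and 0% of 10000 random lists matched on signal had as many higher members as the 47 list genes (median 3, at most 11), which argues against scaling. A p53-independent response to doxorubicin could give this pattern, and it stays a hypothesis found and tested on the same arrays.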

How the results depend on the processing

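Leaving out the wild-type 24 h array, the genes bright on the untreated wild-type array alone, or the genes near clustered bright spots was chosen after the data were seen. The cause of the changes given here was not tested, except where a stricter threshold or filter leaves fewer genes by its construction. Of the 9 higher genes called in wild-type cells 2 lay near clustered bright spots. The rest lost their call with unchanged values when genes near such spots were left out.

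At thresholds of 1.5-fold, of 4-fold and with normexp correction, the genes past the threshold in wild-type cells numbered 7104, 842 and 2357 at 12 h, 7226, 980 and 2279 at 24 h, and 8624, 1945 and 3494 at 48 h. In null cells they numbered 5905, 372 and 1440 at 12 h, 6211, 363 and 1114 at 24 h, and 7790, 1203 and 2142 at 48 h, and with probes well above background on all arrays 1669 at 24 h and 2598 at 48 h. For the difference of responses they numbered 4188, 301 and 750 at 12 h, 5207, 484 and 1196 at 24 h, and 7714, 1074 and 2798 at 48 h. The 1022 genes differing between untreated genotypes became 280 with normexp and 455 with probes well above background on all arrays. The share of higher genes in the 12 h difference went from 57.9 to 45.3% under median scaling, in the 24 h difference from 63.3 to 50.2%, in wild-type cells from 52.8 to 47.9% at 12 h, from 59.2 to 49.5% at 24 h and from 61.6 to 50.9% at 48 h, and in null cells at 48 h from 70.1 to 59.1%. With quantile normalization it went in wild-type cells at 12 h to 49.5% and in the 48 h difference from 48.7 to 51.6%. Under median scaling the median of all genes moved in wild-type cells to -0.21 at 24 h and -0.17 at 48 h.

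The interaction called 0 genes in every alternative but normexp, which called 2, MRGPRG-AS1 and TDRD12, both bright on the untreated wild-type array alone. The null response called 0 in 13 of 13 alternatives. The 18 genes of the wild-type response became 11 with probes well above background on all arrays, and 0 both without the genes bright on the untreated wild-type array alone and without those near clustered bright spots. Leaving out arrays gave from 0 (without 24 h or without 48 h) to 24 (without 12 h), and 1 without the wild-type 24 h array. The 233 genes of the genotype difference became 126 with no filter on dim probes, 484 with probes well above background on all arrays, 29 with no time term, 92 with normexp, 137 with quantile normalization, 429 with trend and robust settings and 575 with the treated arrays alone. Its 163 higher and 70 lower genes became 125 and 89 under median scaling. Leaving out arrays gave from 2 (without 12 h, without 24 h, or without the wild-type 24 h array) to 105 (without 48 h).

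Among values of named genes 1674 of 1846 kept direction and side of the threshold, 157 were no longer past it, 13 came to pass it and 2 reversed. Most of these values belong to genes without a call in the main fit, which had none to lose. The share therefore does not measure how stable the calls are. The BTG2 call in the wild-type response held in 5 of 13 alternatives, and the MAGEA9 genotype call in 15 of 15. Leaving out a time gave null responses from -0.462 (without 48 h) to 0.108 (without 12 h) for BBC3 and from -0.0123 (without 12 h) to 0.840 (without 48 h) for SESN1. Of 144 list medians 137 moved by less than their spread, and of 126 counts of list members passing 108 stayed within 1.5 times. Counts of 0 in both the main fit and an alternative were taken as unchanged, and the value table repeats the main fit. The share of 108 therefore does not measure how stable the calls are. The medians counted came from quantile normalization, median scaling and the mean of a gene's probes, without normexp. Their spread is the SD of a list's medians over the treated times, which is wide where a list changed with time. At 48 h normexp moved the NF-kB median in wild-type cells from 2.28 to 0.94 and the interferon median in null cells from 1.92 to 1.24. The G2/M median in wild-type cells went from -3.02 to -2.83. The value table changed nothing because it holds equal values, so each count of alternatives in which a result held includes this setting that could not fail. No paired analysis was possible because each group has 1 array, beyond time as a term in the genotype difference and in an alternative of the interaction. Signal over background limits the changes of genes not well above background on an array. Single-time changes from such signals are lower limits, while fits used signals as measured, and the lower share of probes well above background in wild-type cells limits what can be seen to fall there.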

Other observations

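The gene families given here were chosen after the values were seen, and limma called 0 of their genes in the wild-type response or the interaction over all genes.

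Aldo-keto reductase genes of the AKR1 family, 8 in number, had median changes of 0.39, 1.92 and 2.69 at 12, 24 and 48 h in wild-type cells and -0.30, 0.48 and 1.64 in null cells. AKR1C3, which reduces prostaglandins and steroids, was not well above background on the untreated and 12 h arrays of either genotype, and differed from untreated by at least 2.86 and 4.11 at 24 and 48 h in wild-type and 1.74 and 3.38 in null cells. AKR1B1, aldose reductase, differed from untreated by 0.26, 2.13 and 2.40 against 0.44, 0.34 and 0.05. With normexp correction the medians were 0.04, 0.69 and 1.26 in wild-type and -0.04, 0.24 and 0.34 in null cells.

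The 6 APOBEC3 cytidine deaminase genes had medians of -0.07, 1.60 and 1.81 in wild-type and -0.14, 0.58 and 1.19 in null cells, and with normexp 0.03, 1.54 and 1.48 and -0.01, 0.26 and 0.36. APOBEC3C differed from untreated by 0.06, 2.06 and 2.62 in wild-type and by -0.38, -0.11 and -0.47 in null cells, and APOBEC3H, not well above background on the untreated and 12 h null arrays, by -0.20, 2.64 and 3.23 in wild-type and at least 1.63 and 2.42 at 24 and 48 h in null cells.

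Metallothionein genes, whose products bind zinc and copper, had medians below 0 in both genotypes. The medians of 10 genes were -0.48, -1.86 and -1.30 in wild-type and -0.78, -1.43 and -0.57 in null cells, and 8 of 10 were at least 2-fold lower at 24 h in each. MT1E differed from untreated by -0.62, -2.05 and -1.57 and by -0.90, -1.84 and -1.11. The 10 genes of exosome components, which degrade RNA, had medians of -0.94, -0.58 and -0.70 in wild-type and -0.37, -0.11 and -0.11 in null cells. Members of the AKR1, APOBEC3 and metallothionein families are close paralogs, and cross-hybridisation between their probes was not tested.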
